A study of Arabidopsis thaliana with 4 samples.

How the data were processed

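Polysomal and non-polysomal RNA of unstressed and dehydrated Arabidopsis plants was hybridized to 4 Affymetrix ATH1 arrays, 1 per group, and the groups were taken from the labels. The deposited table holds a signal intensity for each of 22810 probe sets on a linear scale, and the summary software is not given in the sources used here. The deposited intensities have a mean of 500 on each array after removal of 2% of the values at either end, so the authors' values had been scaled to a common mean. The chip type is given per the file headers of the experiment records, which place both unstressed arrays in 1 hybridization batch and both dehydration arrays in another. No detection calls were used here.

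Each array was brought to an equal 2% trimmed mean, which left the values as they were apart from rounding. Signals under 69.9, the median over the arrays of their percentile 25, were raised to that value, and the log2 was taken. The 64 control probe sets were left out, and a probe set was called measured where its mean log2 signal over the 4 arrays was at or above the median of the other 22746, 7.74, which left 11373. A signal under the lower limit gives only a bound, written as at least or at most. A highest signal of 70.8 was reached by the 27 probe sets for unspiked bacterial sequences, against a median of 11.4.

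Differences of log2 signal were formed for 5 comparisons: polysomal over non-polysomal RNA in either condition, the change of that ratio between conditions, and dehydration over non-stress in either fraction. These share arrays, so that the change in ratio is correlated by construction with the comparisons it is made from. Probe sets at least 2-fold higher or lower were counted. No statistical test or p-value was computed, since each group has 1 array. For the 47 loci with more than 1 measured probe set, the SD of the difference between the brightest and the next probe set was taken.

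A platform annotation, which can be old, gave 13513 probe sets 1 gene symbol and 503 several, while 8730 probe sets other than controls had none here. Of the probe sets with 1 symbol 13436 were matched by gene identifier to the TAIR10.1 gene table, from which current names were taken, and the others kept the annotation's name. Probe sets with several symbols were not named. The measured probe sets held 5979 named loci, each given by its brightest probe set. Many well-known dehydration genes are among the unnamed probe sets, so the lists are partial. Coordinates from the gene table were used only to order the plastid genes along their chromosome. Features of transcripts such as length were not analysed here because no genome sequence was used.

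Genes named in the text are the 10 highest and 10 lowest loci of each comparison, among measured probe sets naming 1 locus and with a signal of at least 4 times the lower limit on the brighter side, together with up to 4 members of each list lying farthest in the direction of its median. These rules, the processing and the alternatives were fixed before the data were examined, apart from 5 alternatives named at the end. Members named outside these rules, such as those lying against a list's median, were chosen after their values were seen.

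Gene lists were described by the median over their measured members and by its percentile among 10000 random lists of the same size matched by decile of mean log2 signal. The random lists draw loci singly. Where members of a list vary together, its percentile can therefore look more extreme than it is. The names and rules of 31 lists were fixed beforehand, some of them given by locus. The other rules were written for gene descriptions and had to be applied to symbols and synonyms, clone names removed, so many found few or no members. The plastid list was taken as genes on the plastid chromosome of the gene table and the mitochondrial list from the annotation's mitochondrial gene names. For 7 of the lists, those of cytosolic and organelle ribosomal proteins, nuclear photosynthesis genes, translation factors, histones, proteasome subunits and aquaporins, loci were added from general knowledge of the genome. This was done after the data had been opened and after the most extreme genes of each comparison had been seen, though not the values of these lists, so their membership is not independent of the data in the way the other lists are. The cytosolic ribosomal protein list rests wholly on such loci. Of the 31 lists, 14 had at least 5 measured members and 10 had none. A further 15 families formed by gene symbol were added after the extreme genes had been seen and are kept to the closing observations. In all 130 list percentiles were computed. Which lists the text leads with, and the size of movement that counts as a difference between settings, were chosen after the list values had been seen.

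The calculations were tested on simulated arrays with an SD of 0.2 on the log2 scale in each array and 200 changed genes. For the comparison of dehydration with non-stress in polysomal RNA, over 11373 probe sets, 100% of genes raised 4-fold and 48.0% of those raised 2-fold, with 38.3% of those lowered 2-fold, passed the 2-fold size, against 0.04% of unchanged ones. Of 40 unshifted lists of 30 genes 3 lay outside percentiles 2.5 to 97.5, and all 40 lists shifted by 0.3 lay above 97.5. Such rates check the calculations and do not carry over to the data, where ratios spread more. The SD of the ratio without stress, on which the lists were simulated, was 0.82 over measured probe sets. Random lists matched to the 9 measured histone genes ran from -0.67 to 0.48 in it (percentiles 2.5 to 97.5), so a shift of 0.3 could be missed there.

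Alternatives were no rescaling, median scaling, quantile normalization, scaling on the 18 hybridization control probe sets, no lower limit, a pseudocount, a limit at percentile 40, no filter, a filter at percentile 75, leaving out suffixed probe sets, sizes of 1.5-fold and 3-fold, and the median over the probe sets of a locus. The 5 alternatives added after seeing the data were list membership by the symbol rule alone, list medians relative to the median of all named loci, the correlation over named loci, the ratio change of probe sets raised by dehydration under each scaling, and the plastid neighbours without a run of 6 genes. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.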

Results

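Messenger RNA of Arabidopsis thaliana was measured on 4 Affymetrix ATH1 arrays, 1 for each combination of growth condition and ribosome loading. Plants were either not stressed or dehydrated, and from each condition non-polysomal RNA (free or carrying a single ribosome) and polysomal RNA (carrying more ribosomes) were hybridized separately. The labels name no tissue. The median signal over 22810 probe sets was 250 for non-stress non-polysomal RNA, 193 for non-stress polysomal RNA, 222 for dehydration non-polysomal RNA and 186 for dehydration polysomal RNA. The lower limit placed on signals, 69.9, lay above 18.8%, 27.4%, 23.0% and 29.2% of the probe sets of these arrays. With 1 array per group there was no replicate check, so no difference was tested and genes are named by size. The number of arrays limits the precision. Between probe sets of the same gene (47 loci), the SD of the difference in log2 ratio ranged from 0.435 to 0.606 over the comparisons. All arrays were scaled to an equal mean, so a ratio of polysomal to non-polysomal signal is relative to the average transcript of the arrays compared and is not the share of a transcript carried on polysomes.

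The polysomal and non-polysomal fractions of unstressed plants were compared to ask which transcripts were relatively rich in polysomes without stress. NRPB7, a subunit of RNA polymerase II, had the highest ratio of the named genes, 3.53 on the log2 scale, with a signal of 78.4 in non-polysomal and 907 in polysomal RNA. The plastid ribosomal protein gene rpl36 was 2.53 higher in polysomal RNA and DRT100, a DNA-damage toleration gene, 2.49 higher. Transcripts encoded in the mitochondrial genome were poor in polysomal RNA, and all 11 measured ones were at least 2-fold lower, or 9 of them under median or hybridization control scaling. DI19, a drought-induced gene, was on the low side, with a signal of 10614.5 in non-polysomal and 1106 in polysomal RNA, a log2 ratio of -3.26.

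Further genes at the high end were AT1G64370 (3.05), AT1G67860 (3.03), AT2G15320 (2.91), AT4G32605 (2.71), AT2G20690 (2.5), AT1G52510 (2.47) and AT1G28400 (2.46). The lowest log2 ratios of the named genes were those of AT1G05340 (-4.15), AT2G06480 (-4.06) and AT2G07739 (-3.70). AT1G32840 was at least 12.2-fold lower, its polysomal signal being under the limit. They were followed by AT5G37130 (-3.38), AT2G07676 (-3.28), AT1G78460 (-3.25), AT5G15360 (-3.20) and AT2G29170 (-3.20). The probe sets of AT2G06480, AT2G07739, AT1G32840 and AT2G07676 carry a suffix that marks probes shared with other sequences.

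The mitochondrial list had a median of -2.06, at percentile 0.0 of 10000 random lists of the same size and brightness, and of -1.95 relative to the median of all named genes. Within it nad4L was at -3.07, nad6 at -2.90, cox1 at -2.65 and nad1 at -2.58. Plastid-encoded transcripts divided: 51 of 69 were below 0, with a list median of -0.36 (percentile 0.0), a direction that was turned by scaling on medians (0.01) or on hybridization controls (0.12). Relative to the median of all named genes it was -0.25. Among the plastid genes psbA was at -1.95, rps14 at -1.53, rpoB at -1.39 and psbN at -1.37, while rpl16 was at 2.05, rpl22 at 1.89 and rps19 at 1.85. Members of the histone, ribosomal protein, nuclear photosynthesis, translation factor and proteasome lists were entered after the extreme genes of each comparison had been seen. Histone transcripts had a median of 0.89 (9 measured, percentile 99.89), with HTB11 at 1.55, AT2G28720 at 1.53 and HTB4 at 1.47. Nuclear genes for organelle ribosomal proteins had a median of 0.80 (9 measured, percentile 98.22), led by AT5G47190 (1.75) and AT1G64510 (1.59). Cytosolic ribosomal protein transcripts lay at 0.15 (107 measured, percentile 58.28), or at -0.06 under quantile normalization, with 11 at least 2-fold higher, 4 at least 2-fold lower and 92 between. Under hybridization control scaling the median was 1.37 for histones, 1.28 for organelle ribosomal proteins (0.53 under quantile normalization) and 0.62 for cytosolic ribosomal proteins (0.52 under median scaling).

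Of 11373 measured probe sets, 973 were at least 2-fold higher and 1348 at least 2-fold lower in polysomal RNA, so that 41.9% of these lay on the high side. Median scaling moved the median of all probe sets by 0.37 and gave 76.1% on the high side, and scaling on the hybridization controls moved it by 0.48 and gave 81.8%. The share also depended on brightness, being 54.8% with the filter at percentile 75 and 29.5% with no filter.

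The same fractions were compared under dehydration. AT1G64370 had the highest ratio of the named genes, 4.06 on the log2 scale, its polysomal signal reaching 9643 against 579 in non-polysomal RNA. AT1G62510 and AT3G53980, both of the lipid-transfer protein family, were at 2.69 and 2.64, and AT3G17520, a late embryogenesis abundant (LEA) family gene, was at 2.61. DI21, a drought-induced gene, had the lowest ratio of the named genes, -4.17, with 2332 in non-polysomal and 129 in polysomal RNA. Cytosolic ribosomal protein transcripts were low in polysomal RNA, with a median of -0.47 (-0.37 relative to all named genes) and 75 of 107 below 0, or a median of -0.21 and 62 below 0 under median scaling.

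NRPB7 was at least 3.36 higher in polysomal RNA, its non-polysomal signal being under the limit. Other high genes were AT1G67860 (3.21), AT1G67865 (3.18), AT2G15320 (2.80), AT3G14067 (2.71) and AT5G07020 (2.64). At the low end stood AT3G62190 (-3.82), AT2G06480 (-3.73), AT4G18975 (-3.41), AT4G00040 (-3.40), AT2G32150 (-3.11), AT1G34110 (-3.11), AT2G35820 (-3.02) and AT1G78460 (-2.96). AT4G00560 was at least 10.6-fold lower, with a polysomal signal under the limit.

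The ribosomal protein list lay at percentile 0.0 of its random lists, with 22 members at least 2-fold lower, 1 at least 2-fold higher and 84 between. AT3G14600 was at -2.14, AT4G39200 at -1.56, AT5G27700 at -1.52 and AT5G47700 at -1.49. Near-identical copies of these genes can share probes, so values of single members are uncertain. Mitochondrial transcripts had a median of -1.45 (percentile 0.0), with cox1 at -1.98, ccb452 at -1.84 and nad4L at -1.78. Dehydration and abscisic acid (ABA) response genes were the list standing highest, with a median of 1.33 (7 measured, percentile 99.99) and all 7 above 0. COR47, a dehydrin, was at 2.11, the dehydrin LTI30 at 1.99, COR15B at 1.53 and COR15A, a chloroplast-targeted cold-regulated protein, at 1.33. Nuclear photosynthesis genes had a median of 0.55 (11 measured, percentile 96.54), with LHCB4.3 at 1.70 and PSBY at 1.18.

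In all, 1030 probe sets were at least 2-fold higher and 1323 at least 2-fold lower, 43.8% on the high side. Median scaling moved the median of all probe sets by 0.26 and the share to 69.5%, and under hybridization control scaling the share was 54.9%. It was 50.4% with the filter at percentile 75 and 37.4% with no filter. Across measured probe sets the ratio under dehydration correlated with that without stress, with Pearson's r of 0.81 and Spearman's rho of 0.803. Genes are not independent replicates, so no p-value was computed. Of the probe sets at least 2-fold higher without stress, 569 were so under dehydration, where independent lists would share 88.1, and of the lower ones 845, where independent lists would share 156.8. None went from 2-fold higher to 2-fold lower, and 15 went from 2-fold lower to 2-fold higher.

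The change in the polysomal to non-polysomal ratio between conditions asked which transcripts gained or lost polysome association relative to the rest under dehydration. AT3G53980, of the lipid-transfer protein family, had a ratio of at most -2.52 without stress and of 2.64 under dehydration, a log2 change of at least 5.17. Its non-polysomal signal was nearly level (402 and 482), while its polysomal signal went from under the limit to 3011. AT3G02480, a LEA family gene, was at least 4.53 higher, AT3G17520 at least 3.61 higher and LEA4-5 at least 3.58 higher. The dehydrin LTI30 was 2.91 higher and the expansin-like gene EXLB1 3.29 higher. In the other direction, 101 of 107 cytosolic ribosomal protein transcripts had a lower ratio under dehydration.

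AT1G05340 was 5.10 higher, AT1G64890 3.05 higher, AT4G33550 2.91 higher and AT2G07739 2.60 higher. The lowest changes of the named genes were those of DI21 (-2.48), AT3G07010, a pectate lyase family gene (-2.11), AT1G04040 (-2.06), rpl16 (-1.90), AT1G20220 (-1.87), HOS3-1 (-1.73), AT3G44330 (-1.69), AT3G08890 (-1.65), AT1G22690 of the gibberellin-regulated GASA family (-1.63) and AT5G57370 (-1.60). For DI21 the polysomal signal without stress was under the limit, so its difference was no larger in size than given, and for AT1G04040, under the limit in dehydration polysomal RNA, it was at least as large.

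The cytosolic ribosomal protein list had a median change of -0.59 (percentile 0.0; -0.60 relative to all named genes), and 9 members were at least 2-fold lower, none at least 2-fold higher and 98 between, while under hybridization control scaling the median was -0.96 and 44 were at least 2-fold lower. AT4G15000 was at -1.40, AT4G39200 at -1.39, AT5G07090 at -1.32 and AT2G17360 at -1.32. Nuclear genes for organelle ribosomal proteins had a median of -0.54 (percentile 1.32; -0.91 under hybridization control scaling), with AT4G17560 at -0.86 and AT5G65220 at -0.83. Dehydration and ABA response genes had a median of 0.63 (percentile 99.94). All 7 were above 0, with 2 at least 2-fold higher and 5 between. Under hybridization control scaling the median was 0.26 and 6 were above 0. Mitochondrial transcripts had a median of 0.61 (percentile 99.96), 4 being at least 2-fold higher, among them ccb206 (1.52) and nad6 (1.38), while under hybridization control scaling it was 0.23 with 2 at least 2-fold higher. The plastid list had a median of 0.10 (percentile 100), which median scaling turned to -0.02 and hybridization control scaling to -0.28. Genes with a conserved peptide upstream open reading frame did not stand apart, with a median of 0.18 (6 measured, percentile 87.0), or 0.07 under median scaling, 0.43 under quantile normalization and -0.19 under hybridization control scaling.

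At least 2-fold changes in the ratio numbered 318 higher and 184 lower probe sets, 63.3% on the high side. That share was 41.2% under median scaling, which moved the median of all probe sets by -0.11, 53.3% under quantile normalization and 10.6% under hybridization control scaling, which moved it by -0.37.

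Polysomal RNA of dehydrated and unstressed plants was compared to ask which transcripts differed among those on several ribosomes. LEA4-5 was at least 6.62 higher on the log2 scale under dehydration, its signal going from under the limit to 6895. SAG29, a SWEET-family sugar transporter gene associated with senescence, was 5.98 higher. AT3G53980 was at least 5.43 higher, AT3G02480 at least 5.12 higher, AT3G17520 at least 4.76 higher and AT2G37870 4.54 higher. EXPA8, an expansin, was at -3.33 and EXO, a growth-related gene, at -2.73.

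AT5G50360 was at least 5.14 higher, AT5G15190 4.78 higher, AT1G05340 4.17 higher and AT3G13672 4.06 higher. Other low genes were AT1G22690 (-4.06), AT1G11850 (-3.37), AT1G47400 (-3.24), AT3G06070 (-3.23), the pectin lyase-like gene AT4G23820 (-3.23), AT5G44020 (-2.71) and AT3G54400 (-2.70). AT1G04040 was at least 12.4-fold lower.

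The dehydration and ABA response list had a median of 2.26 (percentile 100). Of its 7 members 6 were at least 2-fold higher: LTI30 was at 4.04, ALDH7B4, an aldehyde dehydrogenase, at 2.57 and the zinc-finger factor STZ at 2.26, while COR15B was at -0.66. Cytosolic ribosomal protein transcripts had a median of -0.55 (percentile 0.0), with 97 of 107 below 0 and 10 at least 2-fold lower, among them AT4G39200 (-1.45) and AT3G44590 (-1.39). Nuclear genes for organelle ribosomal proteins had a median of -0.65 (percentile 0.79). In the histone list, whose median was -0.04 (percentile 45.29; 0.02 under median and -0.11 under hybridization control scaling), the linker histone HIS1-3, known to respond to drought, was at 3.37.

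There were 723 probe sets at least 2-fold higher and 635 at least 2-fold lower, 53.2% on the high side. That share was 60.4% under median scaling and 46.0% under hybridization control scaling. Both unstressed arrays were hybridized in 1 batch and both dehydration arrays in another, so batch and dehydration cannot be told apart in the effect of dehydration in either fraction or in the change of ratio.

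**Figure D1:**
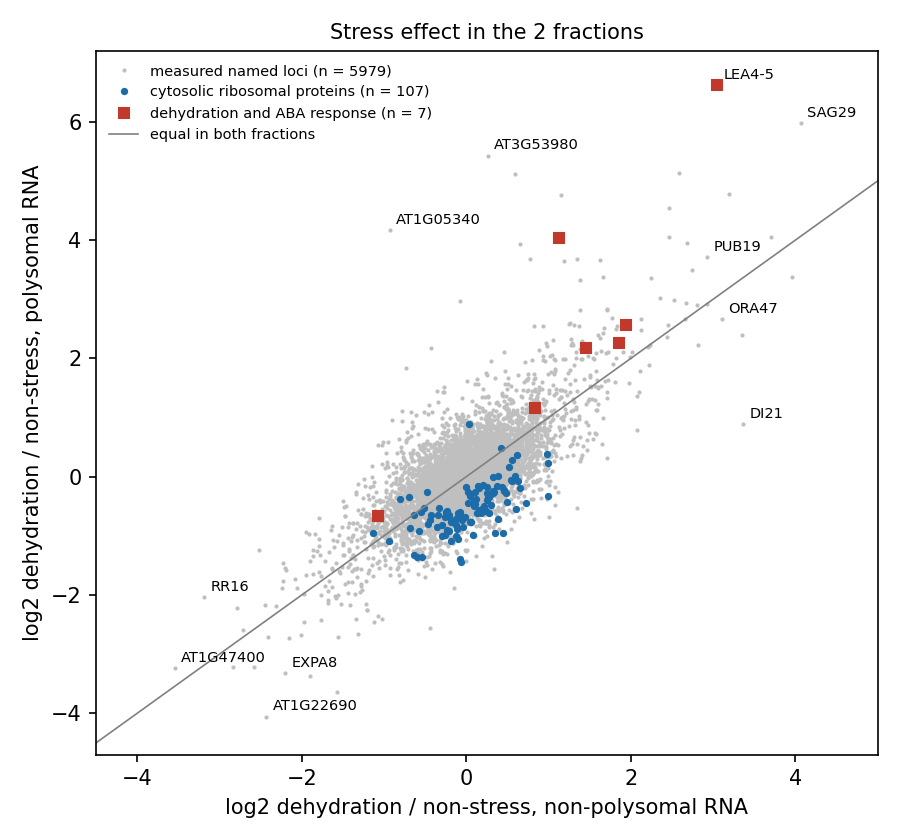
Log2 ratio of dehydration to non-stress signal in polysomal RNA (vertical axis) against that in non-polysomal RNA (horizontal axis) for 5979 measured named loci, with 107 cytosolic ribosomal protein genes as blue dots and 7 dehydration and ABA response genes as red squares, each value from 1 array per group. The line marks equal effects; the ribosomal protein genes lie mostly below it, and AT3G53980 and AT1G05340 far above it.

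In non-polysomal RNA SAG29 was the highest of the named genes under dehydration, 4.07 on the log2 scale, from a signal of 459 to 7700. DI21 was 3.37 higher here, against at least 0.89 in polysomal RNA. ORA47, an AP2-type transcription factor, was 3.11 higher, LEA4-5 3.05 higher and PUB19, a U-box ubiquitin ligase, 2.93 higher. RR16, a response regulator of cytokinin signalling, was at -3.19 and AT1G47400 at -3.54. Cytosolic ribosomal protein transcripts lay at 0.06 (percentile 50.55), with 59 above and 48 below 0, or at 0.23 under median and 0.37 under hybridization control scaling, and 51 were above and 55 below 0 under quantile normalization.

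AT5G45630 was 3.96 higher, AT3G13672 3.71 higher, AT4G27654 3.36 higher, AT5G15190 3.19 higher and AT5G53710 2.93 higher. Low genes were AT3G06070 (-2.84), AT5G54130 (-2.79), AT4G23820 (-2.58), AT1G78460 (-2.45), AT1G22690 (-2.43) and AT5G44020 (-2.41). AT5G19120 was at least 6.59-fold lower and AT1G70985 at least 5.75-fold lower, both being under the limit under dehydration.

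The dehydration and ABA response list had a median of 1.45 (percentile 100), with ALDH7B4 at 1.94, STZ at 1.86 and COR47 at 1.45, while COR15B was at -1.07. Proteasome subunit genes had a median of 0.54 (6 measured, percentile 97.71; 0.85 under hybridization control scaling), with AT5G23540 at 0.80. Ubiquitin ligase genes had a median of 0.35 (7 measured, percentile 96.06; 0.65 under hybridization control scaling), with 4 above and 3 below 0. Plastid-encoded transcripts had a median of -0.13 (percentile 0.11), which was 0.04 under median scaling and 0.17 under hybridization control scaling.

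In this fraction 491 probe sets were at least 2-fold higher and 519 at least 2-fold lower, 48.6% on the high side. Median scaling moved the median of all probe sets by 0.17 and the share to 69.0%, and hybridization control scaling moved them by 0.31 and to 81.8%. The share was 54.0% with the filter at percentile 75 and 37.5% with no filter.

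The effect of dehydration was related between fractions, which share no array. Both effects compare the same hybridization batches, so a batch difference would enter both and cannot be told apart from dehydration here. Where both fractions of a condition came from the same plants, any other difference between the plants would enter both effects too. Across measured probe sets Pearson's r was 0.733 and Spearman's rho 0.646. Of the probe sets at least 2-fold higher in polysomal and in non-polysomal RNA, 340 were in both lists, where independent lists would share 31.2. For lower probe sets the number was 315, against 29.0. None was at least 2-fold higher in 1 fraction and at least 2-fold lower in the other.

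**Figure D2:**
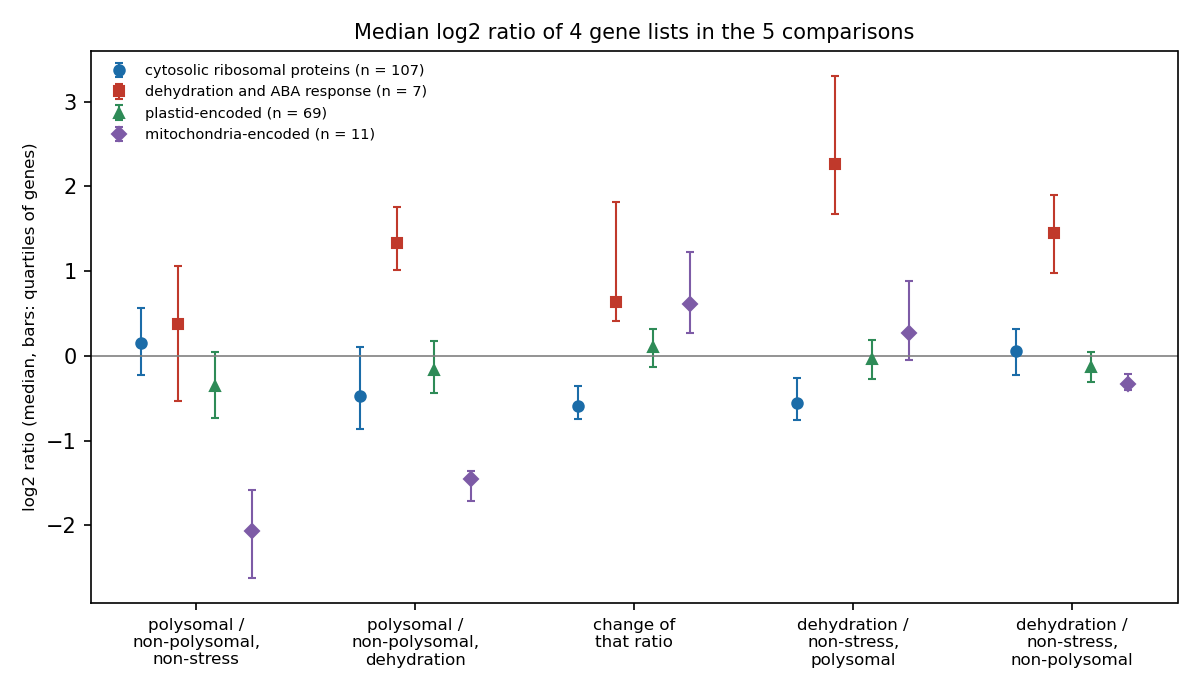
Median log2 ratio (vertical axis) of 4 gene lists in the 5 comparisons (horizontal axis), with bars from the lower to the upper quartile of the measured genes of each list and 1 array per group. The ribosomal protein list lies at 0.15 without stress (-0.06 under quantile normalization) and -0.47 under dehydration and the mitochondrial list at -2.06 and -1.45, while the plastid list changes sign under median scaling in each of the 5 comparisons.

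Translation initiation and elongation factors had a median of 0.46 in the ratio without stress (9 measured, percentile 89.31) and of -0.20 in its change (percentile 22.08), or of 0.94 and -0.57 under hybridization control and 0.83 and -0.31 under median scaling, with AT5G12110 at -1.43. Expansins and xyloglucan endotransglucosylases had a median of -0.07 in the polysomal stress effect (10 measured, percentile 39.22; -0.01 under median and -0.14 under hybridization control scaling), with EXPA8 far below and EXLB1 (3.94) far above it. Cytochrome P450 genes had a median of 0.53 in the ratio without stress (7 measured, percentile 97.32), or of 0.90 under median and 1.01 under hybridization control scaling. Basic leucine zipper factors lay at 0.08 in the polysomal stress effect (10 measured, percentile 64.48), or at 0.14 under median scaling, -0.01 under quantile normalization and 0.01 under hybridization control scaling, and BZIP28 had a change in ratio of 1.01.

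Lists with under 5 measured members are given by their values in the polysomal stress effect. GI, a clock gene, was at 1.07, and FMA, a guard cell lineage factor, at -0.58. The LEA and dehydrin genes found by the list rule, other than LEA4-5, were AT1G54410 at 0.51 and AT2G44060 at 0.67. The other genes called dehydrin or LEA family above were not found by it. Of these COR47 was at 2.17, LTI30 at 4.04, AT3G17520 at least at 4.76 and AT3G02480 at least at 5.12. The tubulin genes found by the list rule, TUA6, TUB9, TUB5 and TUB7, were at -0.37, 0.02, -0.58 and -0.44. WRKY20 was at -0.16 and ZAP1 at 0.13. DFR, an enzyme of anthocyanin synthesis, was at 1.88 and CHIL at -1.51. The rule for aquaporins found 1 measured gene, AQI, which encodes no aquaporin, at -0.54.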

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

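All tests in this part were chosen after the results they bear on had been seen. With 1 array per group, none of the differences between conditions or fractions below was tested, and genes named by size, with the list members taken as examples, are listed where the values in both groups have opposite signs and each exceeds the SD of the difference between probe sets of a locus. The listed values are those with equal-mean scaling. Median and hybridization control scaling moved the median of all probe sets by 0.37 and 0.48 in the ratio without stress. The moves were 0.26 and 0.10 in the ratio under dehydration, and 0.17 and 0.31 in the non-polysomal stress effect. The smaller values listed may thus not exceed that SD under those scalings.

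The ratio of polysomal to non-polysomal signal had opposite signs in the conditions for the following genes. Without stress and under dehydration it was -4.15 and 0.95 for AT1G05340, -2.52 and 2.64 for AT3G53980, -1.0 and 2.61 for AT3G17520, -2.14 and 2.39 for AT3G02480, and -2.33 and 1.24 for LEA4-5. It was -1.22 and 2.07 for EXLB1, -1.36 and 1.69 for AT1G64890, -1.06 and 1.85 for AT4G33550, -0.92 and 1.99 for LTI30, -1.35 and 1.21 for AT5G50360, and -0.81 and 1.26 for AT2G37870. For AT3G53980, AT3G17520, AT3G02480, LEA4-5 and AT5G50360 the value without stress is an upper bound, since the polysomal signal was under the lower limit. AT1G22690 had values of 1.08 and -0.55, and the ribosomal protein genes AT5G07090 and AT3G44590 had 0.63 and -0.69, and 0.80 and -0.51.

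The dehydration effect had opposite signs in polysomal and non-polysomal RNA for others. It was 4.17 and -0.93 for AT1G05340, at least 1.85 and -0.73 for AT1G32840, and 0.75 and -0.72 for AT2G07676. It was -0.72 and 0.83 for rpl36, -0.53 and 1.34 for AT1G20220, -0.69 and 1.0 for AT3G44330, and -1.10 and 0.50 for AT5G57370. Among list members it was 0.83 and -0.51 for rps14, -0.88 and 0.55 for AT5G12110, 0.55 and -0.53 for NRPA1, a subunit of RNA polymerase I, and -0.44 and 0.73 for the ribosomal protein gene AT1G18540.

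A control probe set for 5S ribosomal RNA, used in no comparison, gave a signal of 4383 in non-stress non-polysomal, 846 in non-stress polysomal, 2966 in dehydration non-polysomal and 1765 in dehydration polysomal RNA, all above 70.8, the highest signal of the unspiked bacterial controls.

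Cytosolic ribosomal protein transcripts had a median change in ratio of -0.59. A difference in scaling as the whole source is argued against, since the highest median over 4 scalings was -0.48, with quantile normalization. Brightness by signal decile is also argued against as the whole source, because loci outside the list, drawn from the same deciles, had a median of -0.09. Brightness within a decile was not matched, so an effect limited to the brightest signals was not tested. Hybridization batch and dehydration cannot be told apart, though a batch difference equal in both fractions would cancel in the change of ratio. The hybridization controls themselves had a mean change of 0.37, opposite in sign to that of the list. Scaling on them gave a list median of -0.96. An effect of dehydration on these transcripts may account for the pattern and stays open as a hypothesis.

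Mitochondrial transcripts had a median ratio of -2.06 without stress. Probe sets marked by a suffix as shared do not account for it, since members with unsuffixed probe sets had a median of -2.49 (7 of 11). Sharing that no suffix marks was not tested. The highest median over 4 scalings was -1.58. A loss of all organelle RNA from polysomes is argued against by the plastid median of -0.36. The design holds no group that tests a biological explanation, so none was tested.

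Probe sets raised by dehydration had a higher ratio under it with equal-mean scaling: those at least 2-fold higher in polysomal RNA had a median change of 0.56, but those chosen on non-polysomal RNA had -0.01. Chosen by the mean effect of both fractions, where the SD per probe set was 0.308 in polysomal and 0.337 in non-polysomal RNA, they had a median of 0.36, and signals under the lower limit are argued against as the whole source, since it was 0.33 without probe sets having one on any array. Scaling may account for a value above 0, as hybridization control scaling gave -0.09. Set against all measured probe sets the median was 0.34 with equal-mean scaling but 0.13 with quantile normalization, so neither scaling nor choosing on an array that also enters the change is excluded. The counterpart for probe sets lowered by dehydration was -0.10, batch stays open, and a gain in polysome association of raised transcripts is a candidate explanation that 1 array per group cannot settle.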

How the results depend on the processing

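The tests of 5 settings, list membership by symbol rule alone, list medians relative to all named loci, the correlation over named loci, the ratio change of probe sets raised by dehydration under each scaling and plastid neighbours without a run of 6 genes, were chosen after the results were seen, as were the size of movement taken to matter and the lists described below. No paired analysis was possible because the labels give 1 replicate per group and the results come from no test. Using the deposited values with no rescaling moved 1 of the 10 counts, from 1030 to 1031 higher in the ratio under dehydration, since they already had an equal mean, so it says nothing on stability. With no lower limit, a limit at percentile 40, quantile normalization or without suffixed probe sets, each of the 10 counts of higher and lower probe sets stayed within 1.5 times its value. None of the 100 values of named genes changed sign under any setting that gave a value. They were the extremes of each comparison, the smallest in size being -1.60. No setting moved the median of all probe sets by more than 0.48, so the unchanged signs say little on stability. Signals near the lower limit bound what can be resolved, and a pseudocount in place of it moved 54 of these values by more than the SD of a probe set.

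Where counts differed by more than 1.5 times between settings the cause was not tested, apart from stricter or looser sizes and filters, which change the counts by construction. Counts are given as higher, then lower. For the ratio without stress, they were 2087 and 655 with median scaling, 2489 and 555 with hybridization control scaling, 2248 and 2812 at 1.5-fold, and 190 and 450 at 3-fold, while the lower count was 2630 with no filter and 556 with the filter at percentile 75. For the ratio under dehydration, they were 1778 and 781 with median scaling, 627 and 617 with the filter at percentile 75, 2341 and 2742 at 1.5-fold, and 229 and 388 at 3-fold, and the lower count was 2022 with no filter. For the change in ratio, they were 205 and 293 with median scaling, 103 and 869 with hybridization control scaling, 194 and 121 with a pseudocount, 861 and 358 with no filter, 102 and 79 with the filter at percentile 75, 1264 and 1020 at 1.5-fold, and 68 and 16 at 3-fold. For the stress effect in polysomal RNA, they were 377 and 337 with the filter at percentile 75, 1782 and 1776 at 1.5-fold, and 276 and 175 at 3-fold. For that in non-polysomal RNA, they were 1094 and 244 with hybridization control scaling, 293 and 250 with the filter at percentile 75, 1465 and 1547 at 1.5-fold, and 149 and 134 at 3-fold, the higher count was 773 with median scaling and the lower 1018 with no filter. The correlation of stress effects was 0.629 with no filter.

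Of 130 list medians, hybridization control scaling moved 69 by more than their bootstrap SD, median scaling 47 and quantile normalization 16. Changes of sign, taken up where the median stood apart from its random lists, numbered 3 more under each of hybridization control and median scaling, all in the plastid list. The values below are those of the lists weighed as patterns and of the changes of sign. The cytosolic ribosomal protein median was -0.21 with median scaling and -0.59 with quantile normalization in the ratio under dehydration. In the change of ratio it was -0.70 with median scaling, -0.48 with quantile normalization and -0.96 with hybridization control scaling, and in the polysomal stress effect -0.50 with median and -0.62 with hybridization control scaling. The mitochondrial median without stress was -1.69 with median scaling, -1.58 with hybridization control scaling and -2.49 without suffixed probe sets. Under dehydration it was -1.19 with median scaling, -1.30 with a pseudocount and -1.64 with the filter at percentile 75. The plastid median without stress was -0.53 with quantile normalization and -0.25 relative to all named loci, and it changed sign with median scaling (0.01) and hybridization control scaling (0.12). It also changed sign in the change of ratio, to -0.02 and -0.28, and in the non-polysomal stress effect, to 0.04 and 0.17, under the same scalings. The median of serine carboxypeptidase-like genes in the polysomal stress effect was -0.41 and became 0.19 with the filter at percentile 75. The cause was not tested. By the symbol rule alone, the lists of cytosolic and organelle ribosomal proteins, histones, proteasome subunits and translation factors had too few members for a value, so their values rest on the loci added later.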

Other observations

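The tests in this part were all chosen after the results they bear on had been seen, and the families, formed by gene symbol, after the extreme genes had been seen. Of 15 families 12 had at least 5 measured members. Autophagy genes stood high in dehydration comparisons: 9 measured members, mostly of the ATG8 family, had a median of 0.92 in the polysomal stress effect (percentile 99.96) and 0.54 in the non-polysomal one (percentile 99.66; 0.85 under hybridization control scaling), and their median change in ratio was 0.49 (percentile 99.58), or 0.26 under quantile normalization and 0.11 under hybridization control scaling. ATG8C was at 1.26 and APG8A at 1.09 in polysomal RNA, while ATG8E was at -0.02. UDP-glycosyltransferase genes were rich in polysomal RNA without stress, with a median of 0.77 (15 measured, 11 above 0, percentile 100; 1.25 under hybridization control scaling), and had a median stress effect there of -0.55 (percentile 0.10; -0.36 under quantile normalization). UGT78D1 was at -2.41 and UGT85A5 at 2.56.

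Trichome birefringence-like genes had a median stress effect of -0.70 in polysomal (9 measured, percentile 0.10) and -0.65 in non-polysomal RNA (percentile 0.24; -0.34 under hybridization control scaling), but they divided, 5 of the 9 lying below 0 in polysomal and 7 in non-polysomal RNA, with TBL26 at -1.59 in polysomal RNA. The IQ-domain genes had a non-polysomal median of -0.66 (7 measured, percentile 0.24; -0.35 under hybridization control scaling), with 5 below 0 and iqd21 at -1.44. Nuclear RNA polymerase subunit genes had a median ratio of 0.77 under dehydration (8 measured, percentile 99.82), with 5 above and 3 below 0. Without stress their median was -0.05 (percentile 64.13), and in the change of ratio 0.35 (percentile 95.55). This family was formed after the extreme genes, NRPB7 among them, had been seen. With 130 list percentiles computed, 25 lay in the outer 0.5% at either end. Members of a list can vary together, as neighbouring plastid genes did in the ratio without stress (below). Random lists do not carry this, so that number may be too high.

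Neighbouring plastid genes were closer in ratio than genes in shuffled orders. Along the plastid chromosome, the mean absolute difference in log2 ratio between neighbours was 0.60 without stress, against a median of 0.92 over 10000 shuffled orders (percentile 0.0). Genes rps19, rpl22, rps3, rpl16, rpl14 and rpl36 were at 1.85, 1.89, 1.06, 2.05, 1.74 and 2.53. Without these 6 genes the difference was 0.54 against 0.66 (percentile 0.35). Other neighbours differed widely, such as atpA, atpF and atpH at 0.04, 1.67 and -0.60, and psbZ, rps14 and psaB at 0.05, -1.53 and -0.01. For the change in ratio over all 69 genes the difference was 0.52 against 0.58 (percentile 5.11), and without the 6 genes 0.47 against 0.48 (percentile 47.01). Transcription of neighbouring plastid genes as joint RNAs is a candidate explanation for the 0.60 and the 0.54, and probes reading the same joint RNA would give such values too.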
